A study of Azumapecten farreri with 9 samples.

How the data were processed

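Small RNA was measured in hemocytes, the circulating immune cells of bivalves, of the Zhikong scallop (Azumapecten farreri, also called Chlamys farreri). The 9 libraries form 3 groups of 3, from scallops injected with phosphate-buffered saline (PBS), with normal exosomes, or with exosomes tied to stimulation by lipopolysaccharide (LPS, a bacterial cell wall component). Exosomes are small membrane vesicles that cells release and that carry RNA. Libraries were made with the TruSeq small RNA kit and sequenced on an Illumina HiSeq, and ACGT101-miR removed adapter dimers, junk, low-complexity reads, other structural RNA classes and repeats, per the labels' protocols. The aligner, the genome build and the miRBase release are not given in the sources used here, so no genome positions are printed.

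The deposited table holds 417 lines, each with a name, a sequence and 1 signal value per library, which the deposited file headers call a normalized count. How the authors normalized the counts is not given in the sources used here. The values of each library were found here to be whole multiples of 1 step, read as the worth of 1 read, for 99.55% of the 1990 values above 0, within a tolerance of 0.01 reads. On that reading the libraries held 7063405 to 15676183 reads in the listed lines, and their normalized totals ran from 4002817 to 6337019. The lowest values stood at 5 reads in 8 of 9 libraries, so a value of 0 can hide up to 4 reads and is written as listed at 0. Of the lines, 204 have names starting with PC-, the form ACGT101-miR gives to predicted miRNAs with no registered name, and 213 carry a miRBase name of some species. The prefix (mle, lgi, cte, aca and others) is that species, and suffixes such as R-1 or 1ss10TG mark how the scallop sequence differs from it. Names were taken as listed, and whether each line is a miRNA or a fragment of another RNA was not tested. There were 41 lines that shared their sequence with another line, with identical values, so such lines are 1 measurement listed more than once. The number that ends the name of a predicted line equalled its inferred reads, summed over libraries, for 14 of the 204 and lay below them for 190. Read counts given here are therefore inferred.

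The design had named a test on counts, and a fallback for normalized values, which was used: limma 3.58.1 with trend and robust settings (statmod 1.5.0, R 4.3.3) on log2(value + 1), in 1 model of 3 group means over all 9 libraries, with 6 residual degrees of freedom. Lines with a value of 10 or more in at least 3 libraries were tested, which left 162 lines holding 99.99% of the signal. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over the 162 lines, and a line was called changed at an adjusted p under 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low lines, and no fold is given against a group listed at 0. The labels do not say that the 3 libraries of a group came from separate animals or pools, so p-values measure only the spread between these libraries, which may be technical. An exact permutation test of 3 against 3 libraries cannot go below 0.1.

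Lines to be named were chosen by a rule: for each contrast, the changed lines, up to 10 in each direction, and the next by p to make 10; the 10 lines of highest mean; and for each list its 3 tested members of highest mean plus changed members up to 4. The 12 lists were the let-7 complex, the miR-2/miR-71 cluster, the miR-92 family, the miR-10 family, the numbers miR-1984 to miR-1999, immune-associated families, muscle, neural, epithelial and sensory, gut and endocrine, vertebrate blood and liver, and the predicted candidates. Apart from the predicted candidates, a member is any line whose miRNA number is in the list, whatever its species prefix or suffix. Lists thus hold lines named from vertebrates, and lines that share 1 sequence count as separate members. The 10 lists with at least 3 tested members were tested in the 3 contrasts, 30 tests in all, with limma's camera at a preset correlation of 0.01 and again at an estimated one, and with fry. Camera compares a list with the other lines; fry asks whether the members move, on balance, 1 way, and mixed fry whether they change in either direction, without comparing them with other lines. Groups, tests, lists, the naming rule and the alternatives planned were written before the data were examined.

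The limma step was tested on simulated data for LPS exosomes vs PBS, with the spread of the 162 lines and 40 of them changed in each of 20 rounds: it recovered 30% of the 2-fold and 63.5% of the 4-fold changes, and 2.79% of its calls were false. The simulated values had no floor at 0 and no correlation between lines, so these rates need not hold for lines listed at 0 in a whole group. Alternatives covered 2 other scalings, quantile normalization, 2 other filters, limma without trend and robust settings, the replicate number as a block, fits of 2 groups, pseudocounts of 0.1 and 10, sums by family, and each library left out in turn. Others were added after the results had been seen and are named as such in the closing section. Permutation tests and figures used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.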

Results

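Hemocyte miRNAs were compared between 3 groups of scallops that had received PBS, normal exosomes or LPS exosomes by injection, with 3 libraries per group. The series title places the question in the modulation of immunity by exosomes through miRNAs. The listed lines held 7937843, 10548089 and 9542277 reads in the PBS libraries, 11166747, 12373768 and 15676183 in the normal exosome libraries, and 14493632, 7388060 and 7063405 in the LPS exosome libraries. Pearson's r of log2 values over the 162 tested lines was 0.935 to 0.978 for pairs of libraries within a group (median 0.958) and 0.899 to 0.962 between groups (median 0.936). These are correlations across miRNAs, which are not independent replicates. On the first 2 principal components, with 32.1% and 22.7% of the variance, LPS exosomes replicate 1 stood apart at -15.4 on the first and PBS replicate 1 at 13.9 on the second.

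A few miRNAs made up most of the hemocyte profile in all 3 groups. PC-5p-1_12698927 (TCCCTGAGACCATAACTTGAGA), a predicted line with the seed CCCTGAG of the miR-125 lines, held 43.0% ± 2.92 (SD, n = 9) of the signal. Its first 19 bases are the full sequence of cte-miR-125_R-3_1ss12CA. The next were miR-184-3p with 22.8% ± 1.56 and miR-100, a member of the let-7 complex, with 14.8% ± 2.05. The miR-133-3p line, from a family best known from muscle, held 3.50% ± 0.434, let-7c held 2.92% ± 0.466, and lgi-miR-92_1ss9TC held 2.21% ± 0.929. The remaining lines of the 10 most abundant were miR-96a-5p (1.88% ± 0.335), miR-2b-3p (1.37% ± 0.323), miR-71-5p (0.861% ± 0.131) and miR-1175-3p (0.690% ± 0.0936). Together these 10 lines held 94.1% ± 0.830 of the signal, and none of them passed the limma test in any contrast. Their smallest adjusted p (limma, Benjamini-Hochberg) was 0.165, for lgi-miR-92_1ss9TC in LPS exosomes vs PBS, where it held 1.91% ± 0.209 against 2.93% ± 1.47 (n = 3 each). The differences of miR-184, miR-100, miR-133, let-7c, miR-92 and miR-2a between the exosome groups, and those of miR-184 and miR-71 between normal exosomes and PBS, changed direction when libraries were scaled to equal totals.

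The comparison of LPS exosomes with PBS asks which hemocyte miRNAs differ after vesicles tied to a bacterial stimulus. The predicted line PC-3p-1990_749 (TGTAATTTGTGCTCTCCTC) rose from 0 in each PBS library to 313.2, 234.2 and 146.2 in the LPS exosome libraries (adjusted p = 6.86e-05, limma with Benjamini-Hochberg adjustment). miR-263a-5p, of a family best known from sensory organs of insects, rose 3.35-fold, from 191.3 ± 30.1 to 654.4 ± 193 (SD, n = 3; limma adjusted p = 0.0105). A miR-10b-5p line, of a family encoded in the Hox clusters of animals, rose 2.13-fold from 2198 ± 381 to 4647 ± 498 (limma adjusted p = 0.0193). PC-3p-83_47257 (AAATGCCCCCAGAAATCCTAAA), a predicted line with the seed AATGCCC of miR-365, fell 1.97-fold from 10828 ± 1507 to 5561 ± 1315 (limma adjusted p = 0.0368).

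The other changed lines were listed at 0 in a whole group. mle-miR-1990-3p_1ss10TG and lgi-mir-1990-p3_1ss20AT, of which the second is the first plus 1 base, were at 0 in the 3 PBS libraries. In the LPS exosome libraries the first stood at 12.4, 12.3 and 9.07 and the second at 13.8, 9.86 and 10.2 (limma adjusted p = 0.0105 for each). PC-3p-18918_54 stood at 11.9, 32.0 and 34.7 in the PBS libraries and at 0 in the LPS exosome libraries (limma adjusted p = 0.0104). Among 162 lines, 5 rose and 2 fell, and 39 had an unadjusted p under 0.05. Scaling to equal totals gave 5 higher and 1 lower and moved the median log2 fold change of all lines from -0.06 to 0.11. The lines next by p did not pass: PC-5p-14591_77 (17.3, 11.03 and 13.7 in PBS against 3.64, 0 and 0), miR-216b-5p (log2 fold change 1.02 ± 0.27, SE) and PC-3p-10933_110 (18.4, 16.5 and 19.96 in PBS against 0, 0 and 6.80), with limma adjusted p of 0.0545, 0.0631 and 0.0631.

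The count for LPS exosomes against PBS rested on single libraries. It was 0 without LPS exosomes replicate 1 (21 lines with unadjusted p under 0.05; lowest limma adjusted p 0.0718), 0 without LPS exosomes replicate 2 (23 lines; 0.0595), 1 without PBS replicate 3 and 3 without PBS replicate 2, when the filter was applied again to the 8 libraries left. PC-3p-1990_749 cannot pass that filter without an LPS exosome library; with the 162 lines held fixed, an alternative added after this was seen, the counts were 6, 6, 1 and 3. Calls were lost in 16 of 31 alternatives for PC-3p-83_47257, 10 of 31 for the miR-10b-5p line (among them leaving out each LPS exosome library), 11 of 30 for lgi-mir-1990-p3_1ss20AT, 7 of 25 for mle-miR-1990-3p_1ss10TG, 6 of 26 for PC-3p-18918_54 and 5 of 31 for miR-263a-5p.

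The comparison of normal exosomes with PBS asks what vesicles change without the LPS stimulus. miR-31-5p (AGGCAAGATGTTGGCATAGCTGA), of a family studied in immune and developmental regulation in animals, fell 4.53-fold, from 3487, 3312 and 4290 in the PBS libraries to 1029, 815.7 and 633.3 (limma adjusted p = 0.000983). miR-1994a-3p, of the miR-1984 to miR-1999 block, fell 2.38-fold from 3136 ± 323 to 1320 ± 194 (SD, n = 3; limma adjusted p = 0.00562). A miR-278 line fell 2.91-fold from 131.9 ± 46.9 to 42.8 ± 5.39 (limma adjusted p = 0.0404). PC-3p-9728_126 (TTAGGCCAGAATTACTTCCGA) rose from 0, 5.51 and 0 to 51.1, 55.6 and 72.7 (limma adjusted p = 0.0431).

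Both miR-1990 lines again rose from 0 in PBS. mle-miR-1990-3p_1ss10TG reached 9.08, 10.2 and 5.59 (limma adjusted p = 0.0240) and lgi-mir-1990-p3_1ss20AT reached 6.81, 13.0 and 15.4 (0.0133). PC-3p-18918_54 was at 0 in the 3 normal exosome libraries (limma adjusted p = 0.00694). In all, 3 lines rose and 4 fell, and 27 had an unadjusted p under 0.05. Scaling to equal totals gave 3 higher and 9 lower and moved the median log2 fold change of all lines from -0.00 to -0.22. Next by p came PC-5p-2220_666 (log2 fold change -1.25 ± 0.31, SE), mle-miR-1994a-3p_R-2 (-1.02 ± 0.26) and cel-miR-72-5p_R+2, each with a limma adjusted p of 0.0539. The last of these carries the full miR-31-5p sequence with 2 more bases and stood at 21.6, 15.4 and 22.1 in PBS against 0, 6.49 and 0. Calls were lost under alternatives: miR-278 lost its call in 21 of 31 alternatives, PC-3p-9728_126 in 18 of 30, and mle-miR-1990-3p_1ss10TG and lgi-mir-1990-p3_1ss20AT in 16 of 25 and 16 of 30, against 1 of 31 for miR-1994a-3p and 0 of 31 for miR-31-5p. The count was 2 without PBS replicate 2, without PBS replicate 3, without normal exosomes replicate 1 and without normal exosomes replicate 3, and 3 without normal exosomes replicate 2 or LPS exosomes replicate 1.

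The comparison of the exosome groups asks what the LPS stimulus adds. miR-31-5p was 4.27-fold higher with LPS exosomes, at 3448, 2783 and 4318 (limma adjusted p = 0.00069), and its level against PBS there differed by a log2 fold change of -0.09 ± 0.24 (SE; limma adjusted p = 0.857). The miR-10b-5p line rose 2.45-fold (limma adjusted p = 0.0111), miR-216b-5p rose 2.40-fold from 301.2 ± 45.8 to 719.3 ± 61.5 (0.0314), miR-263a-5p rose 2.48-fold (0.0397) and miR-1994a-3p rose 1.74-fold to 2296 ± 309 (0.0412), all on limma's adjusted p. PC-3p-1990_749 was at 0 in the normal exosome libraries too (limma adjusted p = 6.86e-05), and PC-3p-83_47257 fell 2.12-fold from 11715 ± 2226 (0.0314).

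In this contrast 6 lines rose and 1 fell, and 26 had an unadjusted p under 0.05. Scaling to equal totals gave 7 higher and 0 lower and moved the median log2 fold change of all lines from -0.15 to 0.16. The next by p were PC-3p-552_3225 (log2 fold change -2.13 ± 0.58, SE), lgi-miR-10 (1.38 ± 0.38) and PC-5p-14591_77 (7.94, 12.0 and 13.3 with normal exosomes), each at a limma adjusted p of 0.0826. Calls were lost in 20 of 31 alternatives for miR-263a-5p, 19 for miR-1994a-3p, 15 for miR-216b-5p, 12 for PC-3p-83_47257, 4 for the miR-10b-5p line and 0 for miR-31-5p. The count was 1 without LPS exosomes replicate 1, 2 without LPS exosomes replicate 3, 3 without LPS exosomes replicate 2 or normal exosomes replicate 1, and 4 without normal exosomes replicate 3.

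**Figure D1:**
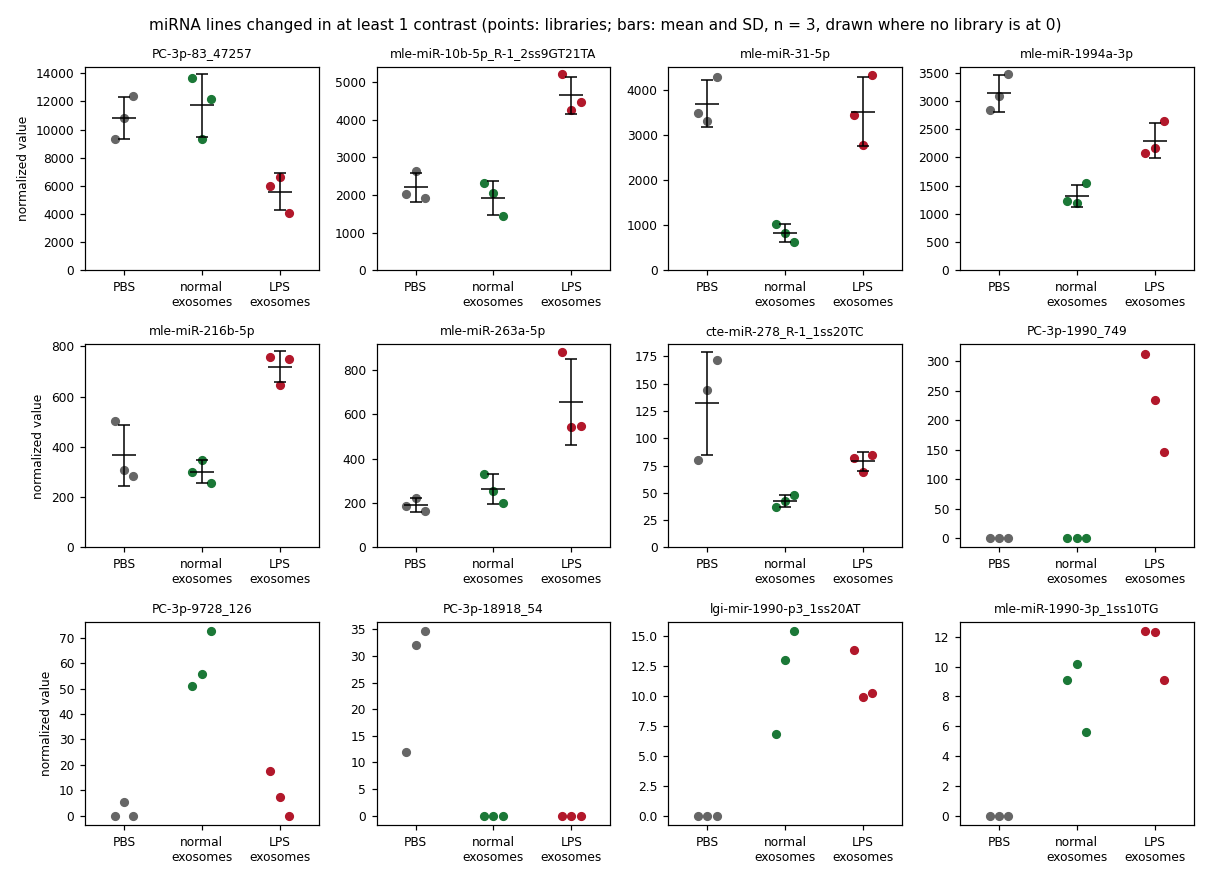
Normalized value (y axis, linear, a scale per panel) of the 12 lines changed in at least 1 contrast, for the PBS, normal exosome and LPS exosome libraries; points are libraries, and bars give mean and SD (n = 3) where no library is at 0. The miR-31-5p points sit at 633.3 to 1029 with normal exosomes and at 2783 to 4318 with LPS exosomes, and those of PC-3p-1990_749 lie above 0 for the LPS exosome libraries alone.

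An F-test over the 3 groups called 10 lines (38 at an unadjusted p under 0.05), and 12 lines were called in at least 1 contrast. The lines called against PBS in both exosome groups were the 2 miR-1990 lines, higher in both, and PC-3p-18918_54, lower in both, all low lines whose calls with normal exosomes were lost in 16, 16 and 9 alternatives. In 100 simulated rounds with shared PBS libraries and no effects, a mean of 0 lines were called in both contrasts with the same sign. That simulation changed no line in any group and drew values without a floor at 0. It therefore cannot say how many calls of low lines would be shared through the PBS libraries. Across the 162 lines the fold changes of both contrasts against PBS had a covariance of 0.718 (simulated with shared PBS libraries and no effects 0.290, 95% range 0.124 to 0.489, and 0.310 with the spread of PBS itself), a Pearson's r of 0.529 (simulated 0.498) and the same sign in 72.2% of lines (simulated 66.6%). The covariance lay above the simulated range, which treats lines as independent, and had a jackknife standard error of 0.147 over the 9 libraries. It was 0.136 over the lines with a mean of 50 or more, 0.19 at a pseudocount of 10 and 0.407 with zeros set to 4 reads, for which no simulation was run, so the covariance depends on how low values are treated.

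**Figure D2:**
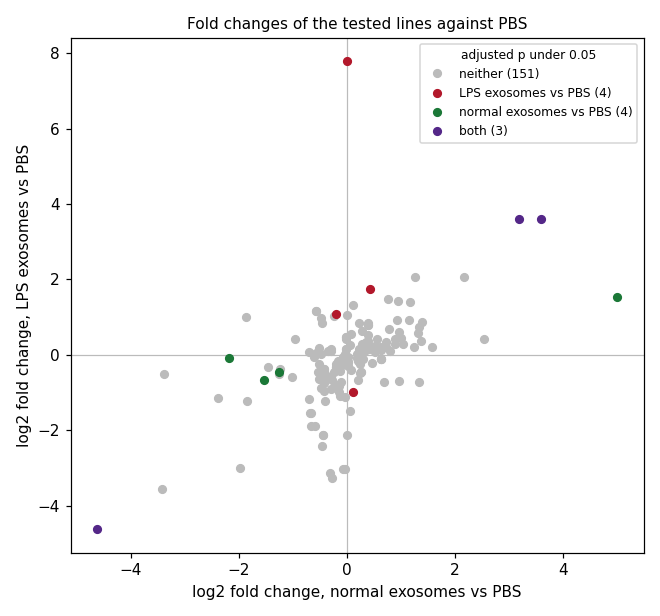
Log2 fold change against PBS for each of the 162 tested lines, with normal exosomes on the x axis and LPS exosomes on the y axis; each point is a line, and colours mark limma calls. Of them, 3 were called in both contrasts, 4 in LPS exosomes alone, 4 in normal exosomes alone and 151 in neither.

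Among the lists, camera called none at adjusted p under 0.05 (lowest 0.193, and 0.836 with an estimated correlation), and fry called 3 of 30 tests for direction and 9 for change in either direction. All 3 directional calls were in the miR-1984 to miR-1999 list, whose 6 tested members had 2 higher and 0 lower with LPS exosomes vs PBS (3 adjusted over the list alone; limma's fry, adjusted p = 1.9e-06), 2 higher and 1 lower with normal exosomes vs PBS (4 adjusted over the list alone; adjusted p = 1.27e-05) and 1 higher between exosome groups (1 adjusted over the list alone; adjusted p = 0.000606). Its median log2 fold changes were 0.71, 0.33 and 0.41. The higher members were the 2 miR-1990 lines and, between exosome groups, miR-1994a-3p, which fell with normal exosomes vs PBS and had a log2 fold change of -0.45 with LPS exosomes vs PBS (limma adjusted p = 0.189). The miR-1990 lines differ by 1 end base and are low lines at 0 in PBS. mle-miR-1994a-3p_R-2, a shorter form of miR-1994a-3p, had log2 fold changes of -0.60 with LPS exosomes and -1.02 with normal exosomes vs PBS. Fry counts such forms as separate members, so its p-values here rest in part on repeat measurements. lgi-miR-1985_R-1, another abundant member, stood at 1706 ± 589, 2085 ± 725 and 2567 ± 384 (SD, n = 3) in PBS, normal exosomes and LPS exosomes.

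The immune-associated list had 29 tested members, of which miR-31-5p changed, lower in normal exosomes and higher between the exosome groups (1 adjusted over the list alone each time; limma's mixed fry, adjusted p = 0.115 and adjusted p = 0.0117). None of its members changed in LPS exosomes vs PBS (0 adjusted over the list alone). The 15 tested lines of the let-7 complex had no change in any contrast, also adjusted over the list alone. Of these, miR-100, let-7c and cte-miR-100_R+1_2ss9CT11AT had log2 fold changes of 0.15, 0.20 and 0.10 with LPS exosomes. PC-5p-1_12698927, which begins with a full miR-125 line, is left out of this list by its name. In the miR-10 family, 1 of 7 changed with LPS exosomes against PBS and against normal exosomes, the miR-10b-5p line (1 and 2 adjusted over the list alone, the second being lgi-miR-10; limma's mixed fry, adjusted p = 0.115 and adjusted p = 0.00232). In the miR-2/miR-71 cluster, 0 of 11 changed, and 1 adjusted over the list alone, mle-miR-2a-3p_R-1 in normal exosomes (log2 fold change 0.53 ± 0.14, SE). In the miR-92 family, 0 of 7 changed, with 0 adjusted over the list alone. Its lines cte-miR-92b and cte-miR-92c share 1 sequence and stood at 35691 ± 8267, 26224 ± 1766 and 26933 ± 1845 (SD, n = 3) in PBS, normal exosomes and LPS exosomes. PC-3p-31_188903, which begins with the full hsa-miR-92b-3p_R-1_1ss21CT sequence, is left out of the miR-92 list by its name.

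For some lists the median, the mean and the tests differed in sign. With LPS exosomes vs PBS, the let-7 complex had a median log2 fold change of 0.14 and a mean of -0.24, the epithelial and sensory list -0.23 and 0.10, and muscle 0.01 and -0.03, while gut and endocrine, at -0.24 and -0.14, was up by camera and down by fry. With normal exosomes vs PBS, gut and endocrine (0.42 and 0.54) was down by fry, muscle (-0.02 and -0.01) was up by camera and fry, and the immune-associated list (-0.03 and 0.00) and the predicted candidates (-0.00 and 0.06) differed between median and mean. Between exosome groups, the miR-10 family (-0.28 and -0.19) and muscle (-0.22 and -0.02) were up by camera and fry.

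Few members of the lists of other cell types passed the test. Of 5 tested muscle members 0 changed, with miR-1-3p at 2876 ± 639 in PBS, 2868 ± 366 with normal exosomes and 2726 ± 1572 with LPS exosomes (SD, n = 3), and aca-miR-133a-3p_L-1R+3 at 55.1 ± 24.7, 53.2 ± 17.2 and 72.9 ± 12.6. The single tested neural member, lgi-miR-7, stood at 545.9 ± 57.5, 504.9 ± 268 and 608.0 ± 211. Of 6 epithelial and sensory members, miR-263a-5p alone passed (1 adjusted over the list alone; limma's mixed fry, adjusted p = 0.00378 for LPS exosomes vs PBS), and miR-96b-5p stood at 253.2 ± 95.8, 169.6 ± 36.9 and 212.3 ± 84.9. Of 4 gut and endocrine members miR-216b-5p passed between exosome groups; 2 passed adjusted over the list alone there and in LPS exosomes vs PBS, the second being miR-375-3p, at 142.5 ± 25.7, 128.7 ± 7.48 and 68.7 ± 22.8. miR-194-5p, of the same list, was at 0, 82.7 and 44.1 in PBS. The single tested member of vertebrate blood and liver, a miR-122-5p line, ran from 21.6 in PBS replicate 1 to 523.7 in normal exosomes replicate 2, which differed more within groups than between them (limma adjusted p = 0.53 and 0.913 against PBS). Of 52 tested predicted candidates, 1 rose and 2 fell with LPS exosomes vs PBS (6 adjusted over the list alone), 1 rose and 1 fell with normal exosomes vs PBS (3), and 1 rose and 1 fell between exosome groups (2), with adjusted p of limma's mixed fry at 8.65e-09, 2.95e-07 and 3.80e-09. Mixed fry does not compare the candidates with other lines, and they include lines at 0 in a whole group, such as PC-3p-1990_749. Limma's camera, which makes that comparison for 1 direction, gave adjusted p of 0.708, 0.945 and 0.507. The abundant candidates PC-3p-31_188903 and PC-3p-33_160524 had log2 fold changes of -0.15 ± 0.17 and 0.35 ± 0.12 (SE) with LPS exosomes.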

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

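The tests in this part were chosen after the results had been seen, apart from the fits under equal totals, median-of-ratios scaling and quantile normalization, which were planned as alternatives. Among the 242 distinct sequences under the filter on low values, 4 lines were above 0 in all 3 libraries of an exosome group and listed at 0 in all 3 PBS libraries, data the comparisons left out. PC-3p-21485_45 had a mean of 15.2 ± 7.84 (SD, n = 3) and PC-5p-24775_36 a mean of 6.20 ± 6.47 with normal exosomes. ssc-mir-1285-p5_1ss15TC had a mean of 14.9 ± 6.13 and PC-3p-20801_47 a mean of 11.04 ± 1.45 with LPS exosomes. The opposite, above 0 in all PBS libraries and 0 in an exosome group, occurred for 2 sequences with normal exosomes and 1 with LPS exosomes.

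PC-3p-1990_749 appeared in the LPS exosome libraries alone, with 860, 380 and 258 inferred reads. Read depth does not account for this: at the lowest LPS exosome rate, normal exosomes replicate 3, the deepest other library, would hold 573 reads and lists 0. The line belongs to 8 lines of 19 or 20 bases within 4 mismatches of its sequence; from PC-3p-1430_1100, seen in all 9 libraries, it differs at 1 base, T13G, with T in PC-3p-1990_749 and G in the other, counted from 1 at the 5′ end of PC-3p-1990_749. The other 7 lines summed to 149.8 ± 48.0 with LPS exosomes and 412.5 ± 161 in the other 6 libraries (difference -262.6, exact permutation p = 0.0357), while all 8 summed to 381.0 ± 91.1 against 412.5 ± 161 (p = 0.798, exact). Of the drop, 69.6% lay in PC-3p-552_3225, 4 mismatches away (means 56.6 and 239.3), and the lines left then had means of 93.2 and 173.1 (exact permutation p = 0.0952); PC-3p-1430_1100 had means of 79.7 and 146.2 (exact permutation p = 0.119), with overlapping values. The family also holds PC-3p-21485_45, above 0 with normal exosomes alone (13.6, 8.34 and 23.8), and PC-3p-31246_25, above 0 in PBS alone (10.8, 6.62 and 9.46), both named after their values were seen. An RNA added to an unchanged family and sequence variants carried by the animals sampled in each group cannot be told apart, since most of the drop lies in 1 line. A response to LPS exosomes stays open and was not tested.

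miR-31-5p was lower in each normal exosome library than in all 6 others. Scaling of the libraries does not account for it: the log2 fold change against PBS was -2.21, -2.40 and -2.05 under median-of-ratios scaling, equal totals and quantile normalization. Nor do reads given to the 1 other listed form, which extends it by 2 bases: its mean differed by -17.55 from PBS, against a difference of 2870 to be made up; forms not listed were not measured. An effect of normal exosomes that LPS exosomes lack, or a difference between the animals sampled, may lie behind the pattern and was not tested.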

How the results depend on the processing

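PC-3p-1990_749 and miR-31-5p kept their calls under every alternative in which they were tested, in both contrasts that called them. PC-3p-1990_749 was not tested when an LPS exosome library was left out and the filter applied again, or when the first PBS and first LPS exosome libraries were left out together, since it then has too few values of 10. Of the 21 calls of named lines, 412 of 618 alternatives kept the call, 206 lost it and 0 reversed it. The alternatives added after seeing the data were merged identical sequences, zeros set to 4 reads, the 2 libraries that stand apart left out, and leaving out a library with the 162 lines held fixed. The last was added after the planned version, which applies the filter again, had been seen to give 0 calls for LPS exosomes vs PBS.

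Leaving out each library with the filter applied again gave 0 to 10 lines in LPS exosomes vs PBS, 2 to 6 in normal exosomes vs PBS, 1 to 10 between exosome groups, 2 to 15 over the 3 groups, and a covariance of 0.583 to 0.752. With the 162 lines held fixed the ranges were 1 to 12, 2 to 8, 3 to 10, 4 to 16, and 0.68 to 0.935. Without both the first PBS and first LPS exosome libraries, LPS exosomes vs PBS had 0 calls by limma (35 at an unadjusted p under 0.05) and the covariance was 0.5.

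For LPS exosomes vs PBS (7), a mean of 50 or more gave 4, 2 groups alone 3, pseudocount 0.1 3 and family sums 11. For normal exosomes vs PBS (7), equal totals gave 12, no filter 4, a mean of 50 3, quantile normalization 2, pseudocount 0.1 2 and the replicate block 3. Between exosome groups (7), limma without trend and robust gave 2 and quantile normalization 3. Over the 3 groups (10), quantile normalization gave 5. The covariance became 0.136 at a mean of 50, 1.79 and 0.19 at pseudocounts 0.1 and 10, 0.92 with family sums and 0.407 with zeros at 4 reads. The stricter filter tests fewer lines; the other causes were not tested.

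The replicate numbers gave no clear sign of pairing: the 9 same-number correlations of deviations ran from -0.303 to 0.291, and 4 of 9 libraries correlated best with their own number. Same-number pairs with a PBS library ran from 0.00204 to 0.291, and those between exosome groups from -0.303 to -0.00319. With so few libraries a group, the check cannot exclude pairing.

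The 16 reversals were all of uncalled values. With equal totals, between exosome groups, miR-184 became 0.0731, miR-100 0.068, miR-133 0.0945, let-7c 0.0754, miR-92 0.107 and miR-2a 0.0449; in normal exosomes vs PBS, miR-184 became -0.0297 and miR-71 -0.0083. Quantile normalization gave 0.0596 for miR-96a in LPS exosomes vs PBS and 0.0939 for let-7c between exosome groups. Leaving out single libraries took let-7c in LPS exosomes vs PBS from -0.0553 (without PBS replicate 1) to 0.344 (without PBS replicate 3), and miR-194 in normal exosomes vs PBS from -0.409 (without PBS replicate 1) to 2.78 (without PBS replicate 2); without PBS replicate 1 and LPS exosomes replicate 1 they became -0.0334 and -0.409. Scaling to equal totals shifts the log2 fold changes of all abundant lines in a contrast by nearly the same amount. The reversals under that scaling follow from this shift. The cause of the other reversals was not tested.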

Other observations

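All tests in this part were chosen after the results had been seen, apart from the splits of the samples and the limma tests. The lines efu-mir-9277-p5 and efu-mir-9277-p3, named here after their values were seen, were lower in both exosome groups without passing the test. The first stood at 56.2, 38.6 and 60.9 in PBS, at 5.67, 0 and 16.1 with normal exosomes and at 0, 8.63 and 7.93 with LPS exosomes (limma adjusted p = 0.171 and 0.142). mle-miR-1989b-5p_1ss11TC, of the miR-1984 to miR-1999 list, had 283.3, 317.6 and 242.7 in PBS and 437.0, 485.7 and 537.2 with LPS exosomes (limma adjusted p = 0.0734, and past the threshold adjusted over the list alone).

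miRNAs of families known from vertebrates varied together between libraries, without following the groups. Lines of the families listed as such (39 listed, 23 present) held 0.00233% to 0.0325% of the signal, highest in normal exosomes replicate 2. Some lines named from vertebrates fall outside the listed families and were left out of that share. Among them were bta-miR-192_R-2, cfa-miR-22 and bta-miR-378, at 75.1, 54.7 and 71.4 in normal exosomes replicate 2. Over 9 libraries miR-122 and the sum of 25 other lines of the listed families had a Pearson's r of 0.837 (exact permutation p = 0.00111, adjusted 0.00222) and a Spearman's rho of 0.933 (exact permutation p = 0.00075, adjusted 0.00222). Without the 2 libraries farthest from the median of miR-122 they were 0.662 and 0.893 (exact permutation p = 0.103 and 0.0123). With 7 libraries and a narrower range of miR-122, this cannot show whether the linear relation rests on those 2 libraries. Against reads, miR-122 had an r of 0.0636 and a rho of -0.133 (exact permutation p = 0.877 and 0.744; adjusted 0.877 for both, over 4 values). The 9 other tested lines of the listed families had a median rho with miR-122 of 0.678, against 0.0833 for 71 lines of like level (p = 0.0006, permutation of lines). Those 71 lines included bta-miR-192_R-2, cfa-miR-22 and bta-miR-378. All these lines come from the same 9 libraries and are not independent, so this p-value does not measure the spread between libraries. RNA from vertebrate material in the libraries could give this pattern, and no biological explanation was tested.

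With 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real splits of LPS exosomes vs PBS, normal exosomes vs PBS and LPS exosomes vs normal exosomes called 7 lines each, and the highest of the others called 0, 2 and 0, so that 1 of 10 splits, the real one, was as large each time. For the 3 groups together, 2 of 100 splits drawn from 280, the real one included, gave 10 lines or more. The highest other gave 10, as many as the real one. So large a count was thus rare among the splits, at a share under 0.05, but not absent, and chance is not excluded. Splits of libraries that may be technical also cannot tell the injections from other differences between the groups.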
